A study of Mus musculus with 8 samples.

How the data were processed

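Retinas of mice were dissociated with papain and single cells were captured in droplets for sequencing from the 3′ end of transcripts, per the labels' protocols. The labels give 3 control libraries, titled WT, and 5 ABCA1 knockout libraries, titled KO. They do not say whether each library came from a separate animal, which part of the gene was deleted or in which cells.

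Per the submitters' processing notes, the authors' tools were Cell Ranger, Seurat 3.1.4 and DESeq2, with GRCm38 as the genome build. The notes do not say for what the authors used DESeq2. The statistical test, the filters on cells, the treatment of doublets and the method of integration are not given in the sources used here. One table of the authors' own comparison was analysed, with 1802 genes and no value per library. Its columns have the names of a Seurat marker table, and its cluster column reads KO in every row, so the first group of each row was taken as the KO cells and the second as the WT cells.

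The log difference in the authors' deposited table was read as a natural log, after the convention of the Seurat version in the submitters' notes, since the file header gives no base. The shares of cells above 0 are fractions from 0 to 1 in the authors' deposited table and are printed here as percent. Both a raw p-value and an adjusted p-value per gene are given in the authors' deposited table, and no error or number of cells. The quotient of adjusted and raw p was 2000 in all 1543 rows in which it could be formed, so the adjustment was taken as Bonferroni over 2000 features. The largest raw p listed was 0.00938, so genes with a raw p of 0.01 or more appear to have been left out. Of the 2000 features, 1802 were listed and 198 were not. A gene that is not listed was therefore in most cases outside those features and not tested. Its absence does not show that it was unchanged.

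A fixed set of 2000 features, and a file title that carries an abbreviation of integrated, point to batch-integrated values and not to normalised counts. Integration moves values between libraries, so a log difference of such values is not a fold change of expression, and a value above 0 is not the detection of a transcript. Differences are therefore called log differences and shares are called shares of cells above 0. The unit of replication behind the p-values is not stated. The table format is one that Seurat uses to compare cells, and p-values that treat cells as replicates do not measure the spread between libraries. The depth per library, the number of cells per library and the spread between libraries are unknown here, so no interval, SD or lower limit of detection is given.

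From the table, genes with an adjusted p under 0.05 were counted as called, in each direction. Before the data were examined, 32 gene lists were fixed, 13 of cell type markers and 19 of pathways, complexes or processes. The list of cytosolic ribosomal proteins was fixed as a rule on gene symbols. Its members are the genes of the table that match the rule, so its unlisted genes were not counted. Each list with at least 5 members was tested in 3 ways, with Benjamini-Hochberg adjustment over 26 lists for each test. Direction was tested with a two-sided Fisher's exact test of higher and lower calls against the other called genes. The mean log difference was tested against 100000 random lists of the same size from the table, in a two-sided permutation test whose smallest possible p is 1e-05. The share of called members was tested with a two-sided Fisher's exact test, and 0 lists passed 0.05 after adjustment. Genes are not independent replicates, and these tests compare a list with the other genes of one table, not KO animals with WT animals.

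The genes named in the text follow a rule fixed before the data were examined. It takes Abca1, the 12 called genes with the largest log difference in each direction, and up to 4 called members of each list with the largest absolute log difference. Some genes that the rule selects are not reported here. Genes named outside that rule are marked as chosen after their values were seen. Fits per library with edgeR or limma were planned for the case that values per library could be had, and were not run. Positions came from the GENCODE annotation of GRCm38, in which 1785 of the 1802 genes (99.1%) matched 1 annotated gene of the same symbol.

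The list tests were checked on simulated data made from the same table. With no shift, 6% of 200 random lists of 12 genes drawn from 1802 genes passed 0.05 in the test of the mean, against 28% with a shift of 0.02 and 95.5% with a shift of 0.05. In the test of direction on 1680 called genes, 5.5% of 200 lists passed at the share of higher calls of the whole table and 100% at a true share of 0.1. Lists with more higher calls than the whole table were not simulated. With 9 of 9 called cone markers higher, the unadjusted p was 0.123 (Fisher's exact test), so lists of that size or smaller could not pass upward. The simulated genes were independent of each other. These rates therefore do not show how often a list of genes that vary together would pass. Alternatives were stricter thresholds of p, other adjustments, minimum differences and shares, the median in place of the mean, lists matched on the share of cells, lists without genes of another list, and directions read against the median gene. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.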

Results

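Single-cell RNA sequencing was carried out on dissociated mouse retina, in 3 libraries from controls (WT) and 5 libraries labelled as ABCA1 knockout (KO). ABCA1 is a membrane transporter that passes cholesterol and phospholipid from cells to apolipoproteins. The comparison addresses how retinal cells differ between libraries labelled as ABCA1 knockout and controls, and the series title places the interest in astrocytes and in disease of the optic nerve. The comparison of KO with WT was read from the authors' deposited table, which pools all cells of each genotype and lists 1802 genes. Its values are differences of natural-log, apparently batch-integrated values (KO minus WT), called log differences below, and they are not fold changes of expression. The table gives no replicate values, errors or sequencing depths, so no difference could be set against the spread between libraries.

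The targeted gene was listed as higher, not lower, in cells of the libraries labelled KO. Abca1, on the minus strand of chromosome 4 from 53030787 to 53159895 in GRCm38, had a log difference of 0.0294 in the authors' deposited table, with an adjusted p of 4.49e-05. For Abca1, 48.7% of KO-labelled cells and 30.5% of WT cells had a value above 0 in the authors' deposited table. That difference of 18.2 percentage points was below the median of 20.8 over all listed genes, so it is not particular to Abca1. Abca1 ranked at 441 from the highest log difference among the 1802 genes of the authors' deposited table. A 3′ sequencing tag that lies outside a deleted part does not check a deletion, and the series title names astrocytes, a small part of the retina. The genotype labels were therefore not checked by these values, and KO below means cells of the libraries labelled KO.

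Crystallins, the structural proteins of the lens family, were prominent among the genes highest in KO, and genes of rod photoreceptors were prominent among those that were lower. The highest called log differences in the authors' deposited table were those of Crygs (0.276), Snhg11 (0.264), Cryba2 (0.263), Meg3 (0.253), Cryba4 (0.245) and Fabp5 (0.240). They were followed in the authors' deposited table by Cryba1 (0.233), Cartpt (0.233), Crybb3 (0.229), Cd24a (0.227), AC149090.1 (0.22) and Crybb1 (0.212). Fabp5 encodes a fatty acid binding protein, Cartpt a neuropeptide precursor and Cd24a a cell surface protein. The lowest were Tma7 (-0.297), Rp1 (-0.263), Gngt1 (-0.25), Pdc (-0.236), Ndufa4 (-0.221) and Rps21 (-0.215) in the authors' deposited table. Next in the authors' deposited table came Cst3 (-0.214), Sag (-0.192), Rcvrn (-0.147), Rps2 (-0.145), Prph2 (-0.142) and Gnat1 (-0.140). Rp1, Gngt1, Pdc, Sag, Rcvrn, Prph2 and Gnat1 encode proteins of photoreceptor outer segments or of the light response.

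At an adjusted p under 0.05, the authors' deposited table called 1680 of its 1802 genes, 1246 of them higher in KO (74.2%) and 434 lower (25.8%). The median log difference of all listed genes was 0.010 rather than 0 in the authors' deposited table. Read against that median, 827 called genes of the authors' deposited table lay above it (49.2%) and 853 below it. Most differences were small, since 42 called genes of the authors' deposited table were above 0.1 and 21 were under -0.1. The quartiles of the log difference were -0.000291 and 0.0289 in the authors' deposited table. Because only genes with a small raw p were listed, every listed member of every fixed gene list passed 0.05 when adjusted over the list alone.

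Marker genes of rod photoreceptors, the cells of dim-light vision that make up most of the mouse retina, had lower values in KO. As for every cell type below, these are values over all cells pooled, not values within that cell type. All 13 listed rod markers passed when adjusted over the list alone, as in every list. Of these 13, 12 were called lower and 0 higher in the authors' deposited table. They included Rp1 (-0.263), a microtubule protein of the outer segment, Gngt1 (-0.25), the rod transducin gamma subunit, Sag (-0.192), rod arrestin, and Rcvrn (-0.147), recoverin, in the authors' deposited table. The mean log difference of the rod markers was -0.131 (permutation test, adjusted p = 6.5e-05), and the direction of their calls differed from that of the other called genes (Fisher's exact test, adjusted p = 1.02e-06). All 13 rod markers had a larger share of cells above 0 in KO than in WT in the authors' deposited table. Rod markers had values above 0 in most WT cells. Of 51 other genes with a WT share of at least 70%, 43 were also lower in KO in the authors' deposited table. Those other genes include the photoreceptor gene Pdc. Against random lists matched on 10 strata of the share of cells, the top one of which spans 62.75% to 99.5% and holds all 13 rod markers, the rod mean passed (permutation test, adjusted p = 0.000130). Within narrower ranges of the WT share it did not pass in a permutation test that was added to the planned ones, with its criterion set before its result was seen (p = 0.0942). The random lists of both matched tests could draw the rod markers themselves, so neither compares rod markers with other genes alone.

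Markers of cone photoreceptors, bipolar cells and amacrine cells had higher values in KO over all cells pooled. All 9 called cone markers were higher in the authors' deposited table, among them the cone arrestin Arr3 (0.173), Pde6h (0.132), Gnb3 (0.124) and Gngt2 (0.0996), and the mean of 10 listed markers was 0.0809 (permutation test, adjusted p = 0.00104). Of 15 called bipolar markers 13 were higher and 2 lower in the authors' deposited table, with Pcp2 (0.125), Gng13 (0.122), Prkca (0.121) and Pcp4 (0.115) in front. The mean over 16 listed bipolar markers was 0.0590 (permutation test, adjusted p = 0.00212). All 7 listed amacrine markers, of 15 looked for, were called higher in the authors' deposited table, including Gad1 (0.109), which makes GABA, Atp1b1 (0.0915) and Pax6 (0.0797). Their mean was 0.0823 (permutation test, adjusted p = 0.00409). The direction of the calls did not pass for cone (Fisher's exact test, adjusted p = 0.397), bipolar (0.580) or amacrine markers (0.475), since most called genes of the table were higher as well. With every called cone and amacrine marker higher, the test could not pass upward (Fisher's exact test, unadjusted p = 0.123 and 0.201). Read against the median gene instead, the direction passed for cone markers (Fisher's exact test, adjusted p = 0.0167) but not for bipolar (0.0619) or amacrine markers (0.182), of which 85.7% were then higher.

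Markers of horizontal cells and of retinal ganglion cells, whose axons form the optic nerve, did not stand apart from the other genes. All 6 listed horizontal cell markers, of 8 looked for, were called higher in the authors' deposited table, among them Slc4a3 (0.0448), Calb1 (0.0288), Sept4 (0.0255) and Onecut2 (0.0207). Their mean was 0.0231 (permutation test, adjusted p = 0.704). Of 18 ganglion cell markers looked for, 12 were not listed. Of the 6 listed, 4 were called higher and 2 lower in the authors' deposited table. Cartpt (0.233) lay far above Rbpms (0.0249) and Slc17a6 (0.0177), and the neurofilament gene Nefh (-0.0240) was lower in the authors' deposited table. The mean of the ganglion cell list was 0.0407 (permutation test, adjusted p = 0.303) against a median of 0.0136.

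Astrocyte markers were close to the median gene of the table. All 5 listed astrocyte markers were called higher in the authors' deposited table, with Gja1 (0.0444), a gap junction protein, Ndrg2 (0.0128) and the intermediate filament gene Gfap (0.0101). Their mean of 0.0182 did not differ from that of random lists (permutation test, adjusted p = 0.833), and 8 further astrocyte markers were not listed. Müller glia, the radial glia of the retina, had 11 markers called higher and 4 lower in the authors' deposited table, led by Dbi (0.103), Vim (0.0801), Apoe (0.0783) and Dkk3 (0.0650). Their mean of 0.0282 did not pass either (permutation test, adjusted p = 0.379).

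**Figure D1:**
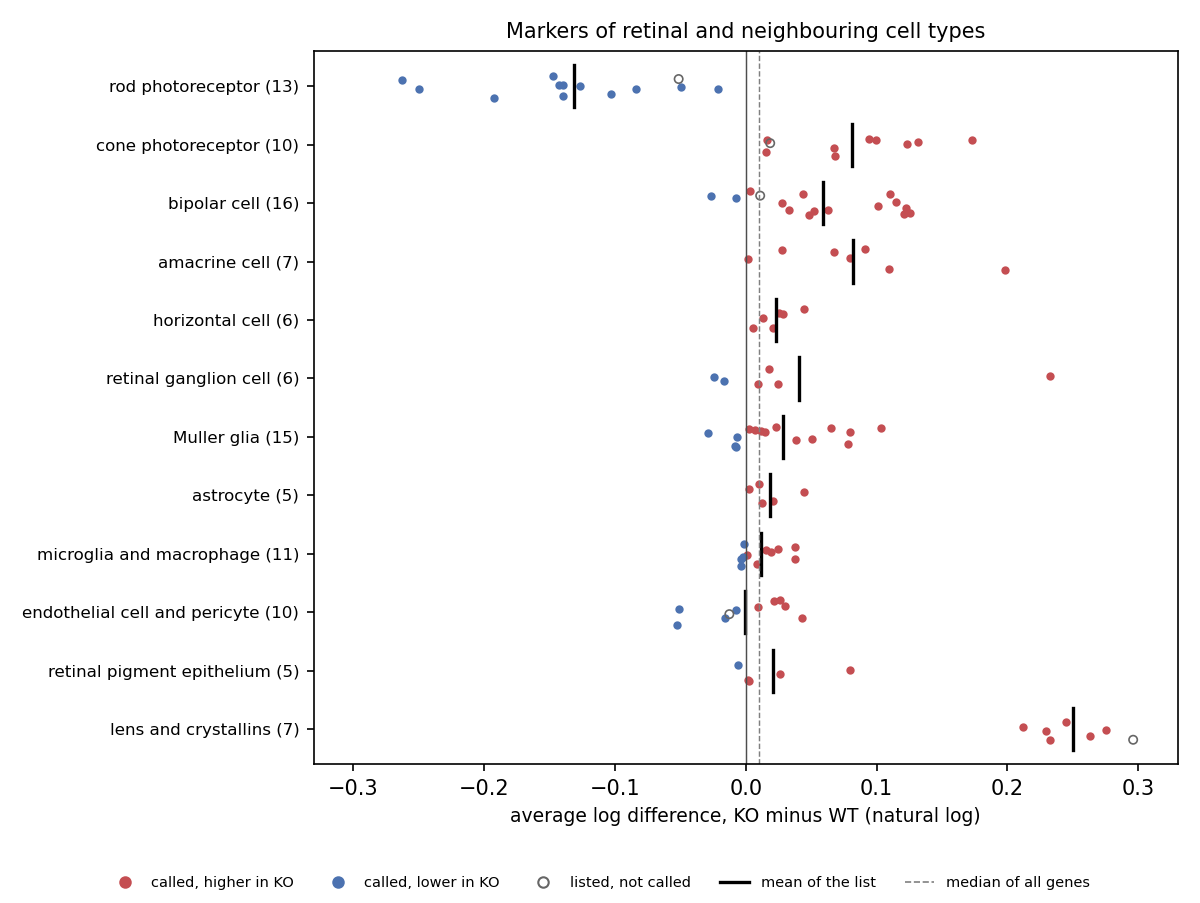
Log difference (natural log, KO minus WT) of each listed marker gene, by cell type with the number of listed markers in brackets. Filled points are called genes, open points listed genes that were not called, bars the list means and the dashed line the median of all listed genes (0.010), and rod markers lie to the left with a mean of -0.131 while crystallins lie farthest to the right with a mean of 0.25.

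Markers of immune, vascular and pigmented cells went both ways. Microglia and macrophage markers were called higher in 7 cases and lower in 4 in the authors' deposited table, with C1qb (0.0373), Ctss (0.0248) and Cx3cr1 (0.0190) among those higher. Their mean was 0.0120 (permutation test, adjusted p = 0.774), and 45.5% of the called markers lay above the median gene. Endothelial and pericyte markers split into 5 higher and 4 lower calls in the authors' deposited table, from Igfbp7 (-0.0522) and the pericyte gene Rgs5 (-0.0507) to Acta2 (0.0428) and Kdr (0.0300), with a mean of -0.000909 (permutation test, adjusted p = 0.358). For the retinal pigment epithelium, 4 markers were called higher and 1 lower in the authors' deposited table, among them Dct (0.0800), Tyrp1 (0.0265) and Lrat (-0.00605). Rdh5 (0.00247 in the authors' deposited table) lay below the median gene, and 40% of the called pigment epithelium markers lay above it. The mean of the 5 pigment epithelium markers was 0.0209 (permutation test, adjusted p = 0.737). Of 6 erythrocyte markers, 0 were listed.

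Crystallins had the highest mean of all lists tested. The 7 listed genes had a mean log difference of 0.25 (permutation test, adjusted p = 6.5e-05), and 6 of them were called higher in the authors' deposited table. Crygs had a value above 0 in 92.0% of KO cells and 73.2% of WT cells in the authors' deposited table, and Cryba4 in 88.1% and 64.5%. These gains, of 18.8 and 23.6 percentage points, lay on either side of the median of 20.8 over all listed genes. Crybb2, chosen after its values were seen, had a log difference of 0.296 and was not called in the authors' deposited table (adjusted p = 0.308). All 6 calls were higher, but the test of direction could not pass upward at that number (Fisher's exact test, p = 0.348 before and 0.580 after adjustment). Another 9 genes of the list, with alpha crystallins and lens membrane proteins among them, were not listed.

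Genes of phototransduction and the visual cycle went both ways. Of 27 listed members, 13 were called higher and 11 lower in the authors' deposited table. Gngt1 (-0.25), Pdc (-0.236), which encodes phosducin, and Sag (-0.192) were lower, and the cone gene Arr3 (0.173) was higher in the authors' deposited table. The mean of the list was -0.0280 (permutation test, adjusted p = 6.5e-05), whereas its median was 0.000110, of opposite sign. A permutation test of the median did not pass (adjusted p = 0.149), nor did the direction of the calls (Fisher's exact test, adjusted p = 0.218).

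Cytosolic ribosomal protein genes were mostly lower in KO. Of 32 listed genes, 20 were called lower and 5 higher in the authors' deposited table. All 32 passed when adjusted over the list alone, as in every list. Those called lower included Rps21 (-0.215), Rps2 (-0.145) and Rpl39 (-0.0890) in the authors' deposited table. The direction of the calls (Fisher's exact test, adjusted p = 4.48e-07) and the mean of -0.0269 (permutation test, adjusted p = 6.5e-05) both passed. Against random lists matched on the share of cells above 0, the mean did not pass (permutation test, adjusted p = 0.153). Of 78 nuclear genes of the respiratory chain only Ndufa4 was listed, as lower, in the authors' deposited table. Of 15 mitochondrially encoded genes 0 were listed, and an unlisted gene is not shown to be unchanged.

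Cholesterol synthesis was nearly unlisted, which does not show that it was unchanged, and cholesterol transport went both ways. Among 25 synthesis genes and SREBP2 targets only Insig1, a sterol-responsive brake on SREBP processing, was listed in the authors' deposited table, with a log difference of 0.0586. Of 11 listed genes of cholesterol efflux, lipoproteins and liver X receptor targets, 6 were called higher and 5 lower in the authors' deposited table. Those with the largest log differences were the desaturase gene Scd2 (0.112), Apoe (0.0783), which encodes an apolipoprotein, the receptor gene Lrp1 (0.0557) and Clu (0.0503) in the authors' deposited table. The mean of the list was 0.0262 (permutation test, adjusted p = 0.489), and Apoe and Clu are also markers of Müller glia.

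Inflammatory genes showed small differences around 0. Chemokines and cytokines had 5 higher and 3 lower calls in the authors' deposited table, with Cxcl12 at -0.0501, Ccl6 at -0.00725, Tgfb1 at 0.00668 and Ccl12 at 0.00450. Interferon response genes had 5 calls in each direction in the authors' deposited table, among them Ifitm3 (-0.0115), Ifi27 (0.00936), Ifit3b (-0.00724) and Ifit3 (-0.00697). The means were -0.00103 for chemokines (permutation test, adjusted p = 0.358) and -0.00200 for the interferon response (permutation test, adjusted p = 0.345). Against random lists matched on the share of cells, neither mean passed (permutation test, adjusted p = 0.177 and 0.141). Read against the median gene, which by construction turns any log difference between 0 and 0.010 lower, Tgfb1, Ccl12 and Ifi27 turned lower, and 0% of the called members of either list lay above it. That split, which was not matched on the share of cells, passed for chemokines (Fisher's exact test, adjusted p = 0.0335) and for the interferon response (Fisher's exact test, adjusted p = 0.0167).

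Antigen presentation, complement and gliosis genes did not stand apart in their means. Antigen presentation had 6 higher and 2 lower calls in the authors' deposited table, with H2-D1 (-0.0473), Tapbp (0.0320), B2m (0.00923) and Psmb9 (0.00602), of which B2m and Psmb9 turned lower against the median gene. The mean of that list was 0.00153 (permutation test, adjusted p = 0.408). Only 12.5% of its called members lay above the median gene, a split that did not pass (Fisher's exact test, adjusted p = 0.182). Complement had 2 higher and 4 lower calls in the authors' deposited table, among them C1qb (0.0373), Serping1 (0.0108) and C4b (-0.00552), and a mean of 0.00486 against a median of -0.00266 (permutation test, adjusted p = 0.606). Of 18 listed genes of reactive astrocytes and gliosis, 9 were called higher and 8 lower in the authors' deposited table, including the small heat shock gene Hspb1 (0.105), Vim (0.0801), H2-D1 (-0.0473) and Cd14 (0.0211). Their mean was 0.0101 (permutation test, adjusted p = 0.704), and 29.4% of the called members lay above the median gene. Of 29 genes of cell death and p53 targets, 2 were listed in the authors' deposited table, both called higher, among them the p53 target Ccng1 (0.0914).

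**Figure D2:**
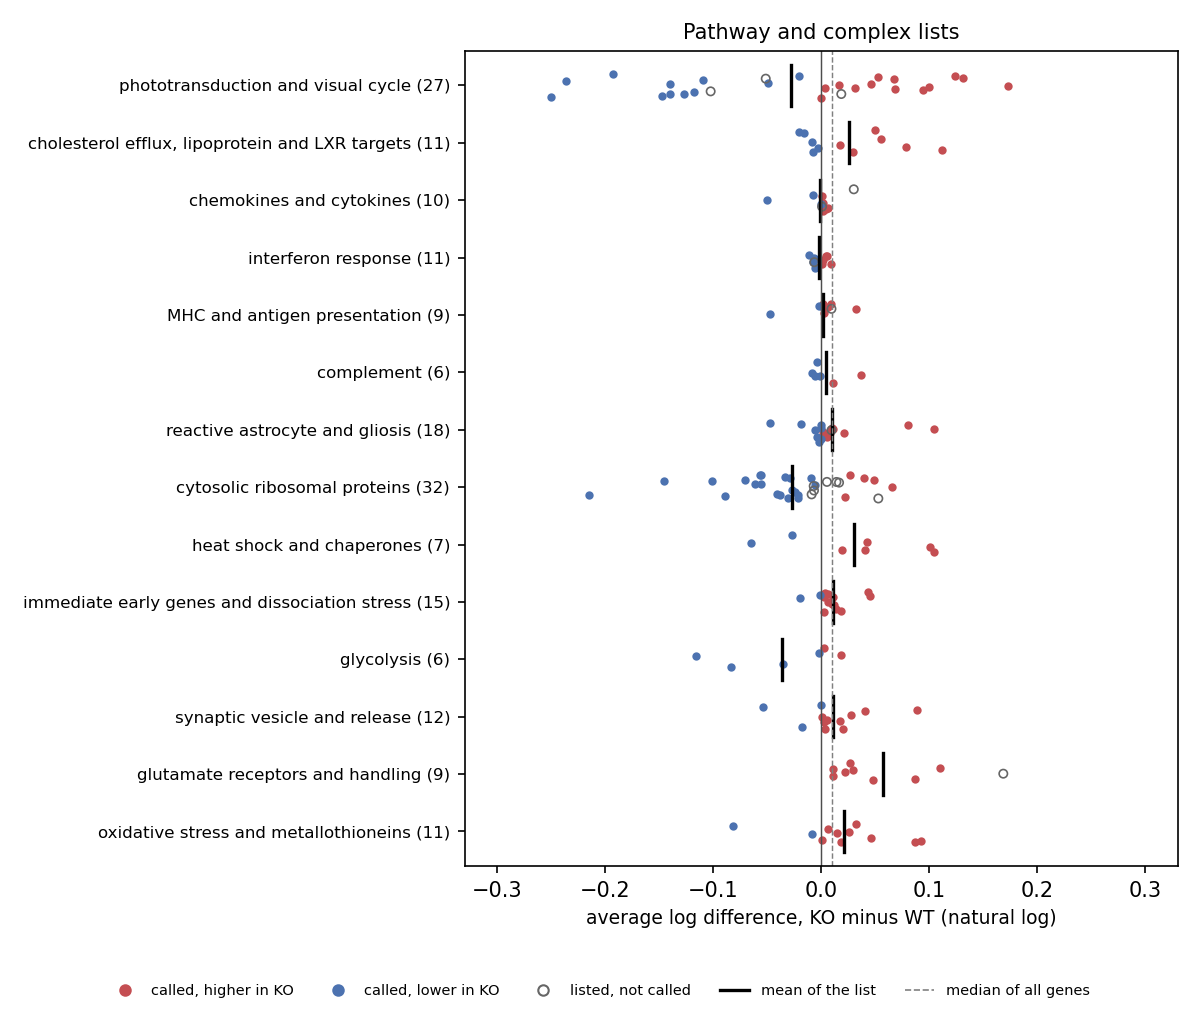
Log difference (natural log, KO minus WT) of each listed gene of the pathway and complex lists with at least 5 listed members, numbers of listed genes in brackets. Filled points are called genes, open points listed genes that were not called, bars the list means and the dashed line the median of all listed genes (0.010), and the ribosomal genes lie mostly left of 0 with a mean of -0.0269.

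Nearly all genes had values above 0 in a larger share of KO cells than of WT cells. The share was larger in KO for 1764 genes (97.9%), smaller for 36 and equal for 2 in the authors' deposited table. The median share was 62.7% in KO and 40.35% in WT, with a median difference of 20.8 percentage points, in the authors' deposited table. Of 466 genes with a lower average in KO, 454 (97.4%) had the larger share in KO in the authors' deposited table. Gfap, for example, had values above 0 in 48.4% of KO cells and 33.2% of WT cells in the authors' deposited table, and the rod gene Gngt1 in 98.9% and 98.6%. Average and share pointed the same way in 1231 called genes, but in 423 called genes of the authors' deposited table the average was lower and the share larger.

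**Figure D3:**
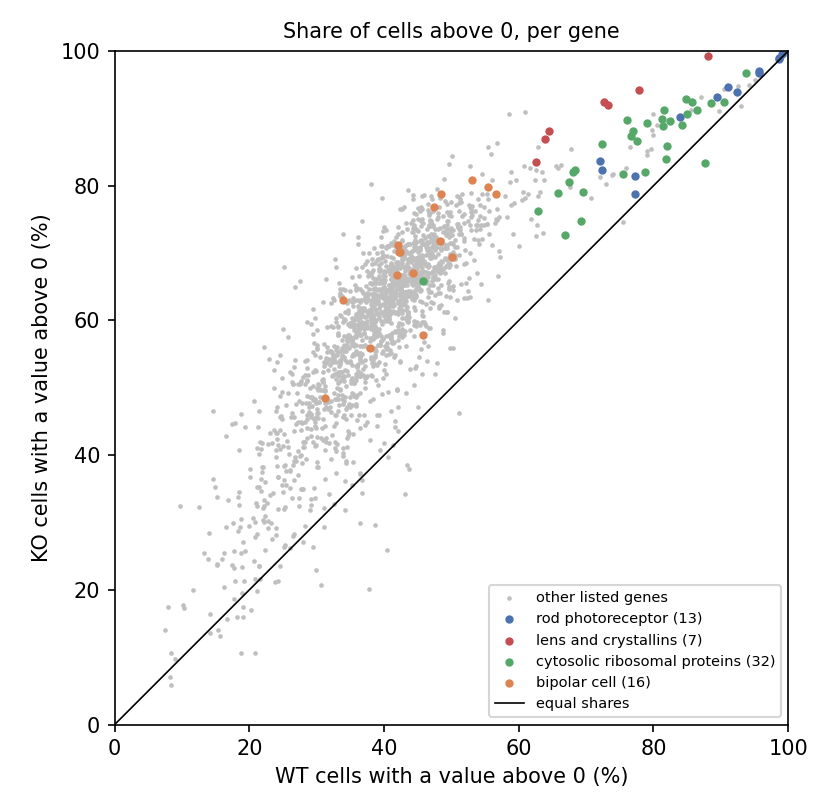
Percent of KO cells (vertical axis) against percent of WT cells (horizontal axis) with a value above 0, 1 point per listed gene, with rod markers, crystallins, ribosomal protein genes and bipolar markers coloured. The line marks equal shares, and 1764 of 1802 genes lie above it.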

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

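The median-centred directions and the requirement that share and average move together were chosen after the data were seen, and the other alternatives before the data were examined. No paired analysis was possible because the table holds no value per library, and for the same reason leaving out a replicate, other splits of the libraries and planned fits per library were not run. Library depth is unknown, so what depth limits could not be assessed. Of 30 alternative counts of called genes, 21 stayed within 1.5 times the main count. At an absolute log2 difference of at least 0.5, or of at least 1, 0 genes were called, 0 higher and 0 lower, since the extremes on the natural-log scale are -0.297 and 0.296. Under median centring 827 were higher and 853 lower, and 11 were lower where share and average had to move together. Of 99 alternative list directions 95 stayed on their side of the threshold. Median centring brought 4 more lists past it by Fisher's exact test: the cone markers (100% higher, adjusted p = 0.0167), glutamate genes (100%, adjusted p = 0.0204), chemokines (0%, adjusted p = 0.0335) and interferon genes (0%, adjusted p = 0.0167), as centring moved the share of higher calls over all genes from 74.2% to 49.2%.

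Of 74 alternative list means 67 stayed on their side. By the median of the list in place of the mean, in permutation tests, phototransduction (0.000110, adjusted p = 0.149), glycolysis (-0.0184, adjusted p = 0.0698) and glutamate genes (0.0293, adjusted p = 0.137) no longer passed, and heat shock genes (0.0403, adjusted p = 0.0496) now did. Against lists matched on the share of cells, ribosomal genes (-0.0269, adjusted p = 0.153) and glycolysis (-0.0359, adjusted p = 0.346) no longer passed the permutation test. Without genes of another list, the glutamate mean of 0.0574 did not pass (permutation test, adjusted p = 0.103). The causes of these changes in list means were not tested. Under median centring 6 named genes reversed, by construction: Rdh5 (-0.00757), Tgfb1 (-0.00337), Ccl12 (-0.00554), Ifi27 (-0.000677), B2m (-0.000816) and Psmb9 (-0.00403). Of 1150 alternative values of named genes, 877 kept their direction and call, 267 lost the call and 6 reversed. The losses include every named gene at the minimum log2 differences of 0.5 and of 1, at each of which 0 genes of the whole table were called.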

Other observations

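The means of the immediate early, heat shock and oxidative stress lists did not pass against random lists. Of 15 immediate early and dissociation stress genes, 13 were called higher and 2 lower in the authors' deposited table, with Fos (0.0454), Btg2 (0.0439), Cyr61 (0.0188) and Junb (-0.0191). Their mean was 0.0107 (permutation test, adjusted p = 0.719), and 46.7% of them lay above the median gene. The 7 heat shock and chaperone genes gave 5 higher and 2 lower calls in the authors' deposited table, and the 2 cytosolic forms of HSP90 differed in sign, with Hsp90ab1 at 0.101 and Hsp90aa1 at -0.0649. Hspb1 (0.105) and Hsp90b1 (0.0427) were called higher in the authors' deposited table, and the mean of the heat shock list was 0.0308 (permutation test, adjusted p = 0.408), whereas its median of 0.0403 passed (permutation test, adjusted p = 0.0496). Of 11 oxidative stress genes 9 were called higher and 2 lower in the authors' deposited table, with the metallothioneins Mt1 (0.0871) and Mt2 (0.0463) higher and the ferritin chains apart, Ftl1 at 0.0921 and Fth1 at -0.0812. The mean of the oxidative stress list was 0.0213 (permutation test, adjusted p = 0.704).

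The mean of the glutamate handling genes lay above the means of random lists, and that of the glycolysis genes below them. The direction of their calls did not pass (Fisher's exact test, adjusted p = 0.397 and 0.218). With all 8 glutamate calls higher, that test could not pass upward (Fisher's exact test, unadjusted p = 0.122). All 8 called glutamate genes were higher in the authors' deposited table, among them the kainate receptor gene Grik1 (0.110), the bipolar receptor gene Grm6 (0.0484) and the transporter gene Slc1a2 (0.0293). The mean over 9 listed glutamate genes was 0.0572 (permutation test, adjusted p = 0.0301). The listed gene that was not called, Gria2 (0.169 in the authors' deposited table), was chosen after its values were seen. It had the largest log difference of the list. Of 6 glycolysis genes, 4 were called lower and 2 higher in the authors' deposited table, with Pkm (-0.116), Eno1 (-0.0838), the glucose transporter gene Slc2a1 (-0.0349) and Hk1 (0.0180), and a mean of -0.0359 (permutation test, adjusted p = 0.0375). Neither list passed when its median was used instead, the glutamate mean did not pass without genes of another list (permutation test, adjusted p = 0.103), and the glycolysis mean did not pass against lists matched on the share of cells (permutation test, adjusted p = 0.346). Synaptic genes had 9 higher and 3 lower calls in the authors' deposited table, with Cplx3 (0.0888), Slc17a7 (-0.0540), Unc13b (0.0404) and Slc32a1 (0.0280). The mean of the synaptic list was 0.0113 (permutation test, adjusted p = 0.737), and 41.7% of its called members lay above the median gene. Of the sex-linked genes, the Y-linked Ddx3y (-0.0559) and Eif2s3y (-0.00852) were called lower and the X-linked Ddx3x (0.0357) higher in the authors' deposited table. Both Y-linked genes had values above 0 in a larger share of KO than of WT cells, 67.2% against 41.9% for Ddx3y and 78.6% against 45.9% for Eif2s3y. The X-linked Eif2s3x (0.0153), chosen after its values were seen, was not called. The sex of the animals was not inferred from these values.

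Of the tests below, those of a shift of values, of the share of rods, of lens carry-over and of a subset of cells were chosen only after the result was seen. The first pattern is the larger share of KO cells above 0 for 97.9% of genes. A shift of all values of one genotype during integration may be behind it, and 97.4% of genes with a lower average had the larger share in KO, but the counts over all genes already fix that percentage at 91.8% or more, so it decides nothing. A lower share of rods among KO cells stays open as well, since the gain of all 6 rod markers with a WT share under 90%, by 1.5 to 11.6 percentage points (exact sign test, p = 0.03125), restates a pattern that nearly all genes share. No value per library was at hand to separate these from an effect of genotype, which was not tested.

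The second pattern is the lower rod markers beside higher markers of other types. A lower share of rods as the whole cause was assumed to raise the markers of all other types alike, an assumption that was not tested. Called markers of cones, bipolar, amacrine, horizontal and ganglion cells were 39 higher and 4 lower against 28 and 12 for Müller glia, astrocytes, microglia and vascular cells (Fisher's exact test, p = 0.0249, and 0.0170 against the median gene). With pigment epithelium markers added, 32 and 13, the split passed too (Fisher's exact test, p = 0.0296, and 0.00656 against the median gene), but with lens markers as well, 38 and 13, it passed only against the median gene (p = 0.0248) and not against 0 (p = 0.0593), so this stays open. A compression of widely detected genes is open too. The rod mean of -0.131 passed against lists matched on wide ranges of the share of cells (permutation test, adjusted p = 0.000130). It did not pass within narrower ranges, where matched lists had a mean of -0.0950 (permutation test, p = 0.0942). The random lists of both tests could draw the rod markers themselves, so the tests cannot decide this. Of 51 other genes with a WT share of at least 70%, Pdc among them, 43 were lower. Their median was -0.0525, against -0.140 for the rod markers. Free RNA of other cells stays open too, since rod markers with a WT share under 90% gained a median of 5.2 points and 41 other genes in that range 7.6; the rod value is below the lower quartile of those genes, 5.7, the bound set beforehand against it, but within the spread of random sets (permutation test, p = 0.145), and a change in rods or other neurons with genotype is open and was not tested.

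The third pattern is the higher crystallins. Lens tissue carried over in dissection may raise them, but of 5 other lens genes looked for 0 were listed, which neither speaks for it nor against it. A subset of KO cells or libraries with very high values could give large differences with weak p-values, and across the 7 crystallins the log difference fell as -log10 p rose (Spearman rho = -0.607, exact permutation p = 0.167), too few genes to decide. Crystallins are also made by retinal neurons and glia, so a genotype effect stays open and was not tested.

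Other hypotheses gave no difference beyond the spread of random lists. Foreign DNA left around a targeted gene could change its neighbours, but the 17 listed genes within 20 Mb of Abca1 had a mean absolute log difference of 0.0231 against 0.0263 for other genes (permutation test, p = 0.713), with medians of 0.0180 and 0.0154. Long noncoding RNAs as a class, prompted by Meg3, had a mean of 0.0128 over 59 genes against 0.0155 for all annotated genes. A class mean at or below that of all genes was the bound set beforehand against a higher class, and it was met. The gap was within the spread of random lists (permutation test, p = 0.611). Snhg11 is annotated as protein coding and was not in that class. Without its highest 2 members, of which Meg3 is one, the mean of the class was 0.00566 (permutation test, p = 0.0687). Only the class was trimmed and not the random lists, which fixes a lower mean in advance, so that p decides nothing. The p-values and sizes of the table did not go together: 183 genes had a p listed as 0 in the authors' deposited table, and 91 of these had an absolute log difference under 0.01. Of the 50 largest absolute log differences in the authors' deposited table, 5 had a p listed as 0 and 2 were not called. Across genes, which are not independent replicates, Spearman's rho of size with -log10 p was -0.0810.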
